A study of Mus musculus with 12 samples.

How the data were processed

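Liver RNA of 12 female C57BL/6 mice was hybridised to Affymetrix mouse arrays, 1 array per mouse and 3 mice in each of 4 groups: vehicle or testosterone at the end of treatment, and vehicle or testosterone after withdrawal. Per the labels' protocols, RNA was extracted with a phenol reagent, digested with DNase, purified on columns, and 5 µg of total RNA was labelled with biotin in a single amplification cycle. The deposited values are linear array intensities, 1 signal per probe set, and the submitters' processing notes name GCOS and MAS5 with their versions not given. The values themselves show that each array had been scaled before deposit: the 2% trimmed mean was 100.05 on every array, so no further scaling was applied. Detection calls, scan dates and any filter before deposit are not given in the sources used here. Mice were assigned to groups by the sample titles. All replicates are separate mice, per the series' design text, and no 2 arrays held the same values. The number of arrays, 3 per group, limits the precision of every comparison.

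The table held 22690 probe sets. After 64 control probe sets were set aside, 20380 of the remaining 22626 had exactly 1 gene symbol in the platform annotation, 691 had several and 1555 had none; only the first kind was named or used for genes. Signals under 4.84, the 25th percentile of all non-control signals, were set to that value before log2. For each of 12393 genes the probe set with the highest mean log2 signal was used, and genes were kept when it lay above the array's median on at least 3 of the 12 arrays, which left 7217. Folds are ratios of geometric means of these signals, whereas means ± SD are arithmetic and of the deposited signals. Where any mouse of the dimmer group lay at or under the floor, the fold is given as at least N-fold, with the floor in place of such signals. No fold is given for such genes where the arithmetic means gave a smaller one.

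Tests used R 4.3.3 and limma 3.58.1 (lmFit and eBayes with a variance trend) on all 12 arrays with 4 group means, so that all groups shared 1 estimate of the spread. All tests were two-sided, p-values were adjusted by Benjamini-Hochberg over the genes tested, and a gene was called at an adjusted p under 0.05. The contrasts were testosterone against vehicle at the end of treatment, the same after withdrawal, the difference between these, and the withdrawal time against the end within each treatment. Gene lists were tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a contrast; lists with under 3 tested members got no test. Agreement in direction between the times was set against the number shared by independent lists and tested with Fisher's exact test. Ratios of 3' to 5' control probe sets were compared by exact permutation tests. The test code was tested on simulated data built from these arrays: for the end of treatment, 31.3%, 76.1% and 97.0% of genes changed by a log2 of 0.5, 1 and 2 were called, with 7 false calls (0.0998% of the genes simulated without change), and for the withdrawal time 35.8%, 80.6% and 98.5%, also with 7. Camera called 0 of 20 lists simulated without change. The genes of these lists were simulated independently, whereas the estimated correlation was, for instance, 0.676 for macrophage markers. The simulation therefore cannot show how often camera calls unchanged lists whose genes move together.

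The groups, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. The rule names, for each of the first 3 contrasts, the 10 largest increases and 10 largest decreases among called genes whose mice of the 2 groups do not overlap (for the difference between the times, called genes with no such condition), up to 4 called members of each list by size of change, and a fixed set of genes whatever their result (among them Esr1, Ghr, Stat5b, Igf1, Hnf4a, Cux2, Bcl6, Xist and Ddx3y). For the contrasts between times it names the 5 largest in each direction, and for genes called at both times the 10 with the largest smaller change. Named outside the rule, after their values were seen, were genes called in opposite directions at the 2 times, single enzymes and acute phase genes by mouse, and the list members that moved against their list (Mup3, Cyp4a14 and Ephx1). The 34 lists were exocrine pancreas enzymes; acinar and pancreatic transcription factors; endocrine pancreas; duct and cholangiocyte; male-biased and female-biased liver genes; growth hormone and STAT5 signalling; steroid receptors and steroid metabolism; xenobiotic P450s and their receptors; phase II conjugation; bile acid synthesis and transport; cholesterol synthesis, fatty acid synthesis, fatty acid oxidation and PPARA targets, and gluconeogenesis and glycogen. The rest were acute phase and complement, unfolded protein response, interferon response, B cells and plasma cells, T and NK cells, Kupffer cells and macrophages, neutrophils, stellate cells and extracellular matrix, endothelial cells, cell division, circadian clock, immediate early and heat shock genes, erythroid and blood, skeletal and smooth muscle, fat cells, intestine and stomach, hepatocyte core genes, sex chromosome check, and fetal liver and dedifferentiation.

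Alternatives changed 1 choice at a time: quantile normalization, median centring, no floor, a pseudocount, a floor at the 50th percentile, no filter, a filter at the 75th percentile, the mean of a gene's probe sets, probe sets with shared-probe suffixes left out, every probe set tested, no variance trend, array weights, only the groups compared, the replicate number as a block, a 2-fold threshold, and each array left out in turn. Added after the data were seen were the actin 3' to 5' ratio as a covariate, the fit without testosterone mice 1 and 2 of the withdrawal time, the gene lists on the contrasts between times, and the alternatives on lists other than the exocrine, male-biased and female-biased ones. No genome was used, so positions of genes are not given.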

Results

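Messenger RNA was measured in the livers of 12 female C57BL/6 mice, an inbred laboratory strain, on 1 Affymetrix array per mouse. Mice had received injections under the skin for 3 weeks, 2 per week, of either 0.9 mg testosterone or 100 µl of the sesame oil vehicle. Livers were taken either at the end of treatment or after withdrawal. Each of the 4 groups held 3 mice. The sample labels give 12 weeks of withdrawal, whereas the series' design text gives 3 weeks, so the length of that interval was left open here. Per the labels, the question was how the hormone acts on gene expression in the female liver at once and over a longer term, and the series title also names exocrine pancreas, the tissue that makes digestive enzymes. Signals below are array intensities, means are given ± SD with n = 3 mice, and log2 changes carry the standard error of the limma fit.

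Median signals of the arrays lay between 20.03 and 22.44. Arrays of the same group correlated at r = 0.977 to 0.988 across probe sets. Xist, the RNA that silences an X chromosome in female cells, read 829 to 1240 on the 12 arrays. The ratio of 3' to 5' signal of beta-actin, which rises when RNA is degraded or incompletely copied, was 2.11 ± 0.077 in testosterone mice and 1.52 ± 0.108 in vehicle mice at the end of treatment. A two-sided exact permutation test gave p = 0.1, the smallest value that 3 mice against 3 allow. The Gapdh ratio was 0.93 ± 0.0254 against 0.763 ± 0.0316 and the pyruvate carboxylase ratio 18.8 ± 2.64 against 6.06 ± 1.35 in the same groups, with p = 0.1 in each exact permutation test. After withdrawal the actin ratio was 1.62 ± 0.179 in testosterone mice and 1.77 ± 0.155 in vehicle mice, with an exact permutation p = 0.2.

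At the end of treatment, the livers of testosterone mice carried much more mRNA for enzymes typical of male mouse liver. Cyp4a12a, a fatty acid hydroxylase, rose at least 127-fold, from 1.05 ± 0.712 to 658 ± 313. Hsd3b5, a steroid dehydrogenase, rose from 21.6 ± 20.5 to 1095 ± 150 (6.10 ± 0.51), and Cyp2d9, a steroid hydroxylase, rose 18.4-fold to 2523 ± 93.8. The sulfotransferases Sult2a2 and Sult3a1 fell at least 401-fold and at least 289-fold, from 2393 ± 368 to 4.70 ± 3.69 and from 1426 ± 321 to 2.01 ± 1.04. The cytochromes Cyp2b13 and Cyp2b9 fell at least 228-fold and 75-fold. Other large increases were those of Nat8f5 (14.1-fold), the fatty acid elongase Elovl3 (8.02-fold), the glucuronosyltransferase Ugt2b38 (7.14-fold), the secreted trefoil peptide Tff3 (at least 5.63-fold), the growth regulator Myc (5.07-fold), the lysosomal nuclease Dnase2a (4.97-fold) and Gadd45g (4.87-fold). Other large decreases were those of the transporters Slc22a26 (at least 74.7-fold) and Slc22a27 (at least 44.9-fold), the metal-binding metallothioneins Mt1 (28.4-fold) and Mt2 (21.1-fold), the fatty acid enzyme Eci3 (at least 15.3-fold) and Lcn2, an iron-scavenging acute phase protein (14.0-fold). Single vehicle mice moved the log2 changes of Hsd3b5 (5.25 without mouse 1, 6.83 without mouse 2), Mt2 (-4.40 with all mice, -3.72 without mouse 2, -5.16 without mouse 3) and Lcn2 (-3.81 with all mice, -2.23 without mouse 2, -4.81 without mouse 3).

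Of 7217 genes tested with limma, 1258 changed at the end of treatment, 680 upward and 578 downward, and 185 of these changed at least 2-fold. At an unadjusted p under 0.05 the count was 2313. The mice of the 2 treatments did not overlap in 35.7% of all genes tested, against 10% by chance. The count was 835 without vehicle mouse 1, 789 without testosterone mouse 1 and 824 without testosterone mouse 2. It was 78 (33 upward, 45 downward) when the actin ratio, which separated the groups of this comparison, was added to the fit. The balance also turned downward with the mean of probe sets (547 upward, 621 downward), every probe set tested (1127, 1217), at 2-fold (75, 110) and without testosterone mouse 2 (405, 419).

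**Figure D1:**
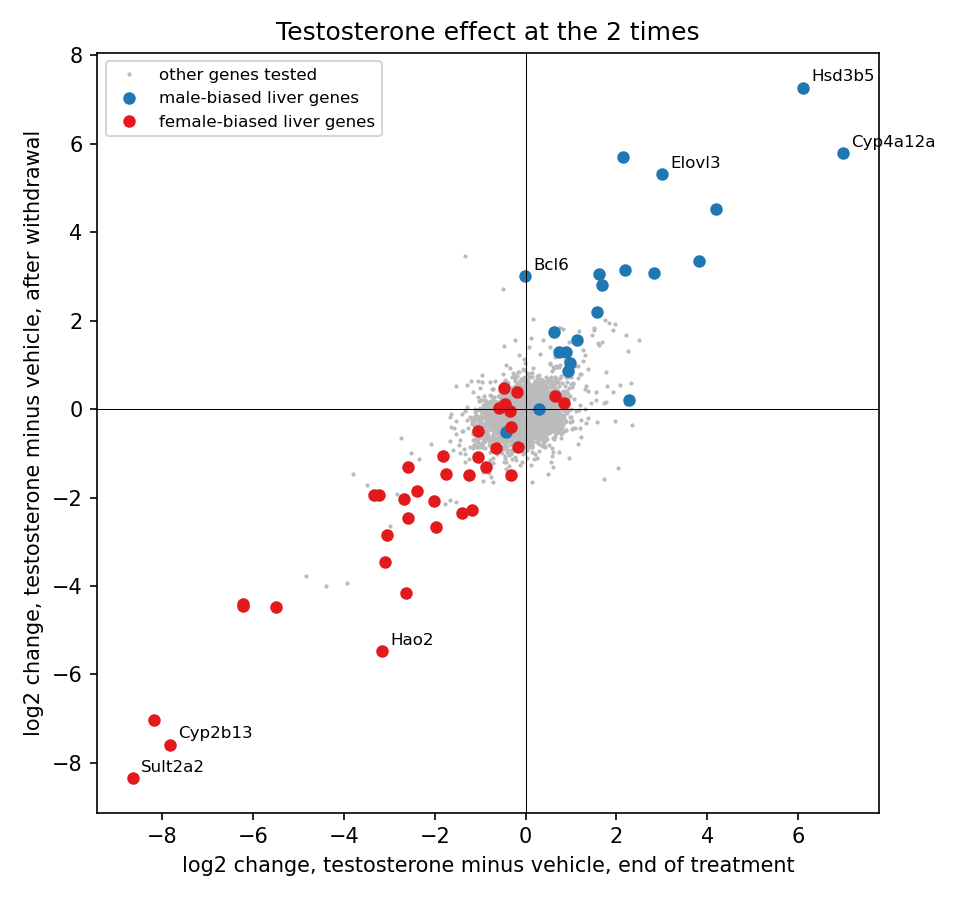
Log2 change in signal, testosterone minus vehicle, at the end of treatment (horizontal axis) and after withdrawal (vertical axis), with 1 point per gene tested. Genes on the fixed lists of male-biased genes (blue) and female-biased genes (red) lie mainly at the upper right and the lower left, with medians of 1.62 and 2.81 for the male-biased list and -1.82 and -1.84 for the female-biased list.

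The list of male-biased liver genes had 21 tested members at the end of treatment. Of these 17 rose, 1 fell and 3 were not called, with a median log2 change of 1.62; adjusted over the list alone, 18 rose and 1 fell. The member that fell was Mup3, a major urinary protein (-0.44, adjusted p = 0.0432). This call was lost with median centring, with no filter and with the actin ratio in the fit, where 0 members were lower. Besides Cyp4a12a, Hsd3b5 and Cyp2d9, the oxysterol hydroxylase Cyp7b1 rose 2.97-fold (1.57 ± 0.19, adjusted p = 8.49e-05) and the glutathione transferase Gstp1 rose 1.96-fold (0.97 ± 0.07, adjusted p = 2.73e-07). The camera test placed the list above other genes at adjusted p = 3.64e-15, and at adjusted p = 0.139 with an estimated correlation. Of 37 female-biased liver genes, 27 fell, 2 rose and 8 were not called, with a median of -1.82; adjusted over the list alone, 29 fell and 2 rose. Cyp17a1, a steroid hydroxylase and lyase, fell 9.38-fold (-3.23 ± 0.16, adjusted p = 3.96e-09), and Cux2, a repressor of male-biased genes, fell at least 6.0-fold, from 29.9 ± 8.18 to 1.23 ± 0.569. The members that rose were Cyp4a14 (0.84) and the epoxide hydrolase Ephx1 (0.66). Camera gave adjusted p = 2.75e-30, and adjusted p = 0.0227 with an estimated correlation. With the actin ratio in the fit, 11 male-biased genes rose and 15 female-biased genes fell, and both lists kept their direction, with medians of 1.79 and -2.02.

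**Figure D2:**
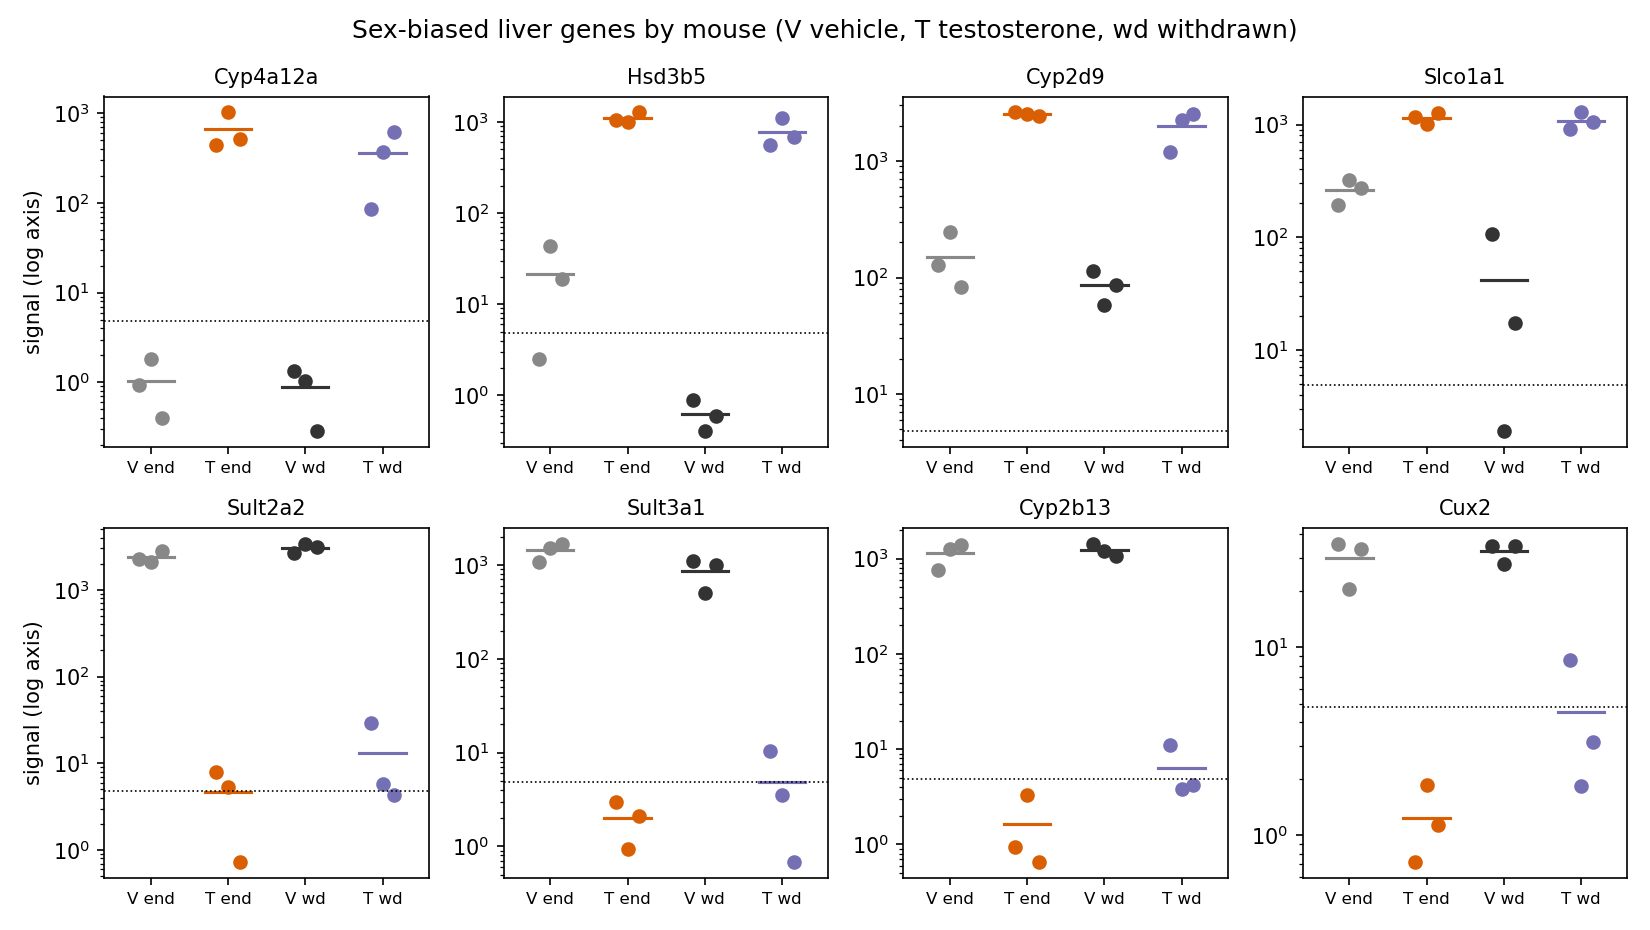
Signals of 4 male-biased genes (upper panels) and 4 female-biased genes (lower panels) on a logarithmic axis, with 1 point per mouse, a line at the mean of each group of 3 and a dotted line at the floor of 4.84 used in the tests. Sult2a2 read 2393 ± 368 in vehicle and 4.70 ± 3.69 in testosterone mice at the end of treatment, and 3058 ± 387 and 13.1 ± 13.9 after withdrawal.

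Of the genes fixed by name, Igf1, the main growth factor induced by growth hormone, fell 1.39-fold (-0.47 ± 0.08, adjusted p = 0.000891), a call that was lost when probe sets shared between transcripts were left out (-0.12). Hnf4a, a liver transcription factor, rose 1.24-fold (0.31 ± 0.09, adjusted p = 0.0289), while another probe set of the gene was called lower. The mean of all probe sets of Hnf4a gave -0.25, and the call was lost without vehicle mouse 1 (0.28), vehicle mouse 2 (0.32), testosterone mouse 1 (0.27) or testosterone mouse 2 (0.26). Not called were the growth hormone receptor Ghr (0.25 ± 0.09), the transcription factor Stat5b (-0.10 ± 0.17), the repressor Bcl6 (-0.01 ± 0.25) and Xist (0.32 ± 0.11). Esr1, the estrogen receptor, lay under the signal filter, and the Y-linked Ddx3y was not analysed here.

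Genes of protein folding in the endoplasmic reticulum rose at the end of treatment. In the unfolded protein response list, 13 of 22 tested members rose, 0 fell and 9 were not called, with 16 and 0 when adjusted over the list alone. Creld2 rose 3.88-fold (1.96 ± 0.25, adjusted p = 0.000121), Sdf2l1 2.76-fold and Manf, a secreted stress protein, 1.93-fold. The list had adjusted p = 1.91e-07 by camera, and adjusted p = 0.191 with an estimated correlation. In the same comparison the actin ratio was 2.11 in testosterone and 1.52 in vehicle mice, and with this ratio in the fit 1 member was called, while camera still called the list higher, with a median of 0.23 in place of 0.46.

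Cholesterol synthesis genes fell: 12 of 19 tested members were lower, 0 were higher and 7 were not called, with a median log2 change of -0.56. Adjusted over the list alone, 16 fell and 1 rose. Hsd17b7 fell 1.84-fold (-0.88 ± 0.15, adjusted p = 0.00148), Sqle, which oxidises squalene, fell 1.82-fold and Dhcr7, which makes cholesterol in the last step, fell 1.78-fold. For the list, camera gave adjusted p = 2.97e-08, and adjusted p = 0.34 with an estimated correlation. The actin ratio was 2.11 against 1.52 here too. With it in the fit 0 members were called and camera did not call the list, whose median was -0.05. In vehicle mice 11 of the 19 members were also lower, and 0 higher, at the withdrawal time than at the end. High signals in vehicle mice of the end and a fall with testosterone therefore cannot be told apart.

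Kupffer cell and macrophage markers and interferon response genes were lower in testosterone mice at the end of treatment. Of 22 macrophage markers 11 fell, 0 rose and 11 were not called, with 15 and 0 when adjusted over the list alone. Examples are the lysosomal protein Cd68 (2.18-fold, -1.12 ± 0.20, adjusted p = 0.00181), the complement subunit C1qb (2.16-fold) and the heme oxygenase Hmox1 (2.25-fold). Of 27 interferon response genes 12 fell, 0 rose and 15 were not called, with 17 and 0 when adjusted over the list alone; Gbp2, a guanylate-binding protein, fell 2.74-fold and the nucleic acid sensor Zbp1 2.54-fold. Camera gave adjusted p = 3.92e-09 and 2.92e-08 for the lists, and adjusted p = 0.34 for each with an estimated correlation. With the actin ratio, 2.11 against 1.52, in the fit, 0 members of either list were called, while camera still called both lists lower, with medians of -0.32 in place of -0.68 and -0.39 in place of -0.49. Without vehicle mouse 2, 9 macrophage markers were lower and 0 higher, with a median of -0.65. Vehicle mouse 1, however, read highest of these vehicle mice for most markers, such as Marco (193 against 71.9 and 73.9) and Csf1r (979 against 686 and 693). It did not for Tyrobp (315 against 377 in mouse 2). Leaving out mouse 2 therefore does not test the influence of mouse 1. The list was also fitted without mouse 1, with values not given here. In vehicle mice 16 of the 22 macrophage markers were also lower, and 0 higher, at the withdrawal time than at the end. High markers in vehicle mice of the end and a fall with testosterone therefore cannot be told apart. Interferon response genes had 1 higher and 2 lower of 27 between those vehicle groups.

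In the acute phase and complement list 12 of 29 tested members fell, 2 rose and 15 were not called at the end of treatment, with 15 and 3 when adjusted over the list alone. Besides the metallothioneins and Lcn2, Orm3, a plasma glycoprotein, fell at least 11.2-fold (-3.49 ± 0.33, adjusted p = 6.43e-06). Camera gave adjusted p = 1.53e-07, and adjusted p = 0.34 with an estimated correlation. Vehicle mouse 2 stood apart from the other vehicle mice, with a signal of 5040 for serum amyloid Saa1 against 379 and 247, and 2010 for Lcn2 against 102 and 56.4. Without that mouse 11 of the 12 genes were still lower, and the change of Lcn2 was -2.23 in place of -3.81. With the actin ratio in the fit 4 members were lower, and camera still called the list lower, with a median of -0.26 in place of -0.35.

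Among other metabolic lists at the end of treatment, phase II conjugation had 3 members higher, 10 lower and 15 not called of 28, with the sulfotransferase Sult1a1 lower by 1.85-fold (adjusted over the list alone 3 and 10; camera adjusted p = 0.0336, lost at adjusted p = 0.344 with an estimated correlation). The list's call was also lost without vehicle mouse 2 (median -0.08) or testosterone mouse 1 (-0.05) or 2 (-0.08), against a median of -0.07 with all mice. Adding the actin ratio, 2.11 against 1.52, to the fit also ended it, with a median of 0.05 and 1 member higher and 1 lower. Xenobiotic P450s and their receptors had 4 higher and 7 lower of 22 (5 and 10 adjusted over the list alone; camera adjusted p = 0.0567). Cyp2c39 fell at least 7.09-fold and Nr1i3, the receptor CAR, 2.23-fold. Steroid receptors and steroid metabolism had 7 higher and 3 lower of 17 (8 and 3; adjusted p = 0.753), and bile acid synthesis and transport 6 higher and 5 lower of 27 (8 and 5; adjusted p = 0.583). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, fell 2.89-fold (-1.53 ± 0.20, adjusted p = 0.000139), and Akr1d1, a steroid reductase, fell 2.19-fold. Growth hormone and STAT5 signalling had 5 higher and 3 lower of 18 (6 and 3; adjusted p = 0.753), led by Onecut1, which rose 3.41-fold, and Cish, a STAT5-induced inhibitor, which rose 3.33-fold. Fatty acid synthesis had 1 higher and 3 lower of 21 (1 and 3; adjusted p = 0.241), fatty acid oxidation and PPARA targets 7 higher and 3 lower of 29 (8 and 3; adjusted p = 0.241), and gluconeogenesis and glycogen 1 higher and 2 lower of 17 (1 and 2; adjusted p = 0.107). The thioesterase Acot3 fell 10.1-fold and its relative Acot1 rose 2.94-fold.

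Of 12 cell division genes 5 fell and 0 rose at the end of treatment (5 and 0 adjusted over the list alone), among them cyclin Ccnd1 (2.74-fold) and thymidine kinase Tk1 (2.15-fold); camera gave adjusted p = 0.014, and adjusted p = 0.34 with an estimated correlation, and the list was not called without vehicle mouse 2 (median -0.24 in place of -0.38). When the actin ratio, 2.11 against 1.52, was in the fit, 1 member was lower, and camera still called the list, with a median of -0.78. Immediate early and heat shock genes had 5 higher and 0 lower of 18 (5 and 0; adjusted p = 0.346), hepatocyte core genes 1 higher and 3 lower of 25 (1 and 3; adjusted p = 0.243), and the sex chromosome check 1 higher and 0 lower of 4 (3 and 0; adjusted p = 0.0567), this being Kdm6a, an X-linked demethylase (1.83-fold). Erythroid and blood genes had 2 higher of 3 (2; adjusted p = 0.0732), with Alas2, the heme synthesis enzyme of red cells, up 3.36-fold. Of 17 circadian clock genes 0 were called by limma, or when adjusted over the list alone (adjusted p = 0.899).

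Markers of other cells and tissues gave few calls at the end of treatment. Stellate cells and extracellular matrix had 1 higher and 2 lower of 20 (1 and 2 adjusted over the list alone; camera adjusted p = 0.0772), endothelial cells 0 and 2 of 18 (0 and 0; adjusted p = 0.144), neutrophils 0 and 1 of 3 (0 and 1; adjusted p = 0.241), and fat cells 1 and 1 of 6 (1 and 1; adjusted p = 0.939). Intestine and stomach had 2 and 0 of 5 (2 and 1; adjusted p = 0.355), fetal liver and dedifferentiation 0 and 2 of 4 (0 and 2; adjusted p = 0.0732), and B cells and plasma cells 0 and 0 of 4 (0 and 1; adjusted p = 0.213). The stem cell marker Prom1 fell 6.15-fold. Acinar and pancreatic transcription factors had 2 higher and 0 lower of 6 (2 and 0; adjusted p = 0.44), these being Onecut1 and Foxa2 (1.5-fold), which hepatocytes also express. Exocrine pancreas enzymes had 1 higher and 0 lower of 3 tested (1 and 0; adjusted p = 0.759). Endocrine pancreas had 1 member tested and duct and cholangiocyte 2, with 0 called and no list test; T and NK cells and skeletal and smooth muscle had 0 members above the filter. Median, mean and test differed in sign for the exocrine enzymes (-0.20, 0.01, upward), bile acid genes (0.02, -0.01, downward) and fat cells (0.05, -0.08, downward).

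After withdrawal, the genes with the largest changes were again enzymes and transporters of sex-biased expression. Hsd3b5 was at least 154-fold higher in testosterone mice (0.633 ± 0.241 in vehicle, 778 ± 277 in testosterone), Cyp4a12a at least 55.4-fold, Elovl3 39.6-fold (31.04 ± 6.04 and 1253 ± 393) and Cyp2d9 22.9-fold. The organic anion transporter Slco1a1 was higher by a log2 change of 5.69 ± 0.69 (41.8 ± 56.2 and 1083 ± 184). Cyp2b13 was at least 192-fold lower and Sult3a1 at least 130-fold, and the log2 changes of Sult2a2 and the hydroxyacid oxidase Hao2 were -8.34 ± 0.46 (3058 ± 387 and 13.1 ± 13.9) and -5.47 ± 0.35 (375 ± 49.4 and 9.01 ± 7.04). Igfbp1, a binding protein of insulin-like growth factors, rose 11-fold with a wide spread, from 53.4 ± 14.6 to 876 ± 916. Further increases were those of Nat8f5 (10.2-fold), the complement component C6 (8.84-fold), Ugt2b38 (at least 8.40-fold), Susd4 (8.24-fold) and Bcl6 (8.04-fold), and further decreases those of Slc22a27 (22.1-fold), Slc22a26 (21.9-fold), Cyp2b9 (21.3-fold), Prom1 (17.8-fold), Mt2 (16.0-fold) and Eci3 (at least 15.3-fold). Log2 changes moved by single vehicle mice were those of Slco1a1 (6.87 without mouse 1, 4.64 without mouse 2). Leaving out single testosterone mice moved Sult2a2 (-9.16 without mouse 1), Cyp4a12a (5.79 with all mice, 6.62 without mouse 1, 5.20 without mouse 3), Cyp2b9 (-4.41 with all mice, -3.45 without mouse 2, -5.02 without mouse 3) and Igfbp1 (3.46 with all mice, 4.27 without mouse 2, 2.59 without mouse 3).

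In all, 433 genes changed after withdrawal by limma, 198 upward and 235 downward, of which 124 changed at least 2-fold. With each array centred on its median the balance turned, to 264 upward and 167 downward, and a filter at the 75th percentile gave 201 and 193. By limma 1485 had an unadjusted p under 0.05. The mice of the 2 treatments did not overlap in 25.9% of all genes tested, against 10% by chance. The count was 236 without vehicle mouse 2, 256 without vehicle mouse 3, 266 without testosterone mouse 2 and 253 without testosterone mouse 3. It was 263 with the actin ratio in the fit, and 250 without testosterone mice 1 and 2, the only mice with several pancreatic enzymes.

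Of 21 male-biased liver genes 18 rose, 1 fell and 2 were not called after withdrawal (18 and 1 adjusted over the list alone), with a median of 2.81 and camera adjusted p = 1.47e-34 (adjusted p = 0.012 with an estimated correlation). Of 37 female-biased liver genes 29 fell, 0 rose and 8 were not called (30 fell and 2 rose adjusted over the list alone), with a median of -1.84 and adjusted p = 3.79e-33 (adjusted p = 0.012 with an estimated correlation). Cux2 was at least 5.53-fold lower (-2.47 ± 0.32, adjusted p = 0.000152). Unfolded protein response genes rose again, 12 of 22 with 0 lower (16 and 0 adjusted over the list alone), at adjusted p = 2.91e-17 (adjusted p = 0.0161 with an estimated correlation). Creld2 rose 3.77-fold, Sdf2l1 3.19-fold, Herpud1, which acts in protein disposal, 2.96-fold and Manf 2.87-fold. Interferon response genes were lower, 8 of 27 with 0 higher (20 and 0 adjusted over the list alone), at adjusted p = 1.53e-10 (adjusted p = 0.153 with an estimated correlation), led by the GTPase Igtp (2.88-fold). Ghr (0.20), Stat5b (-0.26), Hnf4a (0.18), Igf1 (0.06) and Xist (-0.07) were not called.

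Cholesterol synthesis genes gave 0 calls by limma among 19 after withdrawal, also when adjusted over the list alone (camera adjusted p = 0.652), and macrophage markers 0 of 22 (0; adjusted p = 0.362). The actin ratio was 1.62 in testosterone and 1.77 in vehicle mice in this comparison. Acute phase and complement genes had 1 higher and 4 lower of 29 (4 and 4 adjusted over the list alone; adjusted p = 0.539), with Mt1 13.7-fold and Hamp2, a hepcidin, 4.24-fold lower. Bile acid synthesis and transport had 5 higher and 1 lower of 27 (6 and 1; adjusted p = 0.00832, lost at adjusted p = 0.0857 with an estimated correlation), with Cyp7b1 up 4.61-fold and Cyp8b1, which makes cholic acid, up 1.89-fold. Steroid receptors and steroid metabolism had 5 higher and 1 lower of 17 (6 and 2; adjusted p = 0.0113, lost at adjusted p = 0.306 with an estimated correlation). Fatty acid synthesis had 0 higher and 2 lower of 21 (0 and 5; adjusted p = 0.00323, lost at adjusted p = 0.465), and hepatocyte core genes 2 higher and 0 lower of 25 (6 and 0; adjusted p = 0.000198, lost at adjusted p = 0.465). Fetal liver and dedifferentiation had 0 higher and 2 lower of 4 (0 and 3; adjusted p = 0.00068, lost at adjusted p = 0.0774), erythroid and blood genes 2 and 0 of 3 (2 and 0; adjusted p = 0.0113, lost at adjusted p = 0.0922) with Alas2 up 4.03-fold, and stellate cells and extracellular matrix 0 and 1 of 20 (0 and 1; adjusted p = 0.00733, lost at adjusted p = 0.445). B cells and plasma cells had 0 higher and 1 lower of 4 (0 and 2; adjusted p = 0.0208, lost at adjusted p = 0.109). All the p-values given as lost are with an estimated correlation. Without vehicle mouse 1 the stellate (median -0.20) and B cell lists (-0.84) were not called, and fatty acid synthesis was not called without testosterone mice 1 and 2 (-0.18 in place of -0.40). Under quantile normalization hepatocyte core (0.00), bile acid (0.03) and steroid metabolism genes (0.06) were not called and acute phase genes were called lower (-0.18), and with no filter steroid metabolism (0.06), erythroid (-0.03), fetal liver (-0.08) and B cell genes (-0.26) were not called. Macrophage markers were called lower without vehicle mouse 2 (-0.35 in place of -0.12) and with the actin ratio in the fit (-0.25).

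The other lists were not called after withdrawal. Growth hormone and STAT5 signalling had 2 higher and 3 lower of 18 (2 and 3 adjusted over the list alone; adjusted p = 0.805), xenobiotic P450s 3 and 3 of 22 (7 and 5; adjusted p = 0.982), with Cyp2b10 lower by 5.06-fold, and phase II conjugation 4 and 4 of 28 (6 and 6; adjusted p = 0.982). Fatty acid oxidation and PPARA targets had 2 and 3 of 29 (3 and 3; adjusted p = 0.539), gluconeogenesis and glycogen 1 and 1 of 17 (1 and 2; adjusted p = 0.522), immediate early and heat shock genes 2 and 0 of 18 (3 and 0; adjusted p = 0.0583), and circadian clock genes 1 and 2 of 17 (1 and 2; adjusted p = 0.803). Among the clock genes the repressor Bhlhe40 fell 2.17-fold. Acinar and pancreatic transcription factors had 0 higher and 1 lower of 6 (0 and 2; adjusted p = 0.362), and intestine and stomach 1 and 0 of 5 (1 and 0; adjusted p = 0.289). By limma 0 members were called in the neutrophil (3 tested; adjusted p = 0.765), endothelial (18; adjusted p = 0.765), cell division (12; adjusted p = 0.765), fat cell (6; adjusted p = 0.803) and sex chromosome lists (4; adjusted p = 0.373), and 0 when adjusted over each list alone. Duct and cholangiocyte had 1 of 2 lower and endocrine pancreas 0 of 1, too few for a list test. Median, mean and test differed in sign for growth hormone signalling (-0.08, 0.03, downward), phase II conjugation (-0.10, -0.09, upward), fatty acid oxidation (0.06, -0.09, upward) and fat cells (-0.01, -0.01, upward).

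Digestive enzymes of the exocrine pancreas appeared on the arrays of testosterone mice 1 and 2 after withdrawal. Carboxypeptidase Cpa1 read 40.3 and 138 in these mice, against 0.472 in the third mouse and 0.492 to 1.67 in vehicle mice of that time. Carboxypeptidase Cpb1 read 45.8 and 105, chymotrypsinogen Ctrb1 70.4 and 172, trypsin Prss2 69.9 and 142 and colipase Clps 35.9 and 88.1. Of 25 enzymes with a probe set, 7 in mouse 1 and 12 in mouse 2 lay above 5 times the highest vehicle signal or 5 times the floor of 4.84, whichever was higher, against 0 on each of the other 4 testosterone arrays. Only 3 enzymes passed the signal filter. Of these Cela1, an elastase, rose 3.57-fold after withdrawal (1.84 ± 0.22, adjusted p = 8.18e-05), from 116 ± 38.1 to 413 ± 117, and was higher in 3 of 3 mice. At the end of treatment Cela1 rose 1.66-fold (0.73 ± 0.22, adjusted p = 0.0329), a call lost without vehicle mouse 1 (0.63) or 2 (0.74) or testosterone mouse 1 (0.71) or 3 (0.65). The enzyme list after withdrawal had 1 member higher and 0 lower of 3 (2 and 0 adjusted over the list alone), with camera adjusted p = 0.00198, lost at adjusted p = 0.0573 with an estimated correlation. With no filter 25 enzymes were tested, with 1 higher, 0 lower and a median of 1.79. Camera then gave adjusted p = 2.94e-10 at the preset correlation, though Cpa1, for one, stood out in mice 1 and 2 alone. In the list of 3, Cela2a passed the filter through vehicle mouse 1 of the end (52.1) and testosterone mice 1 and 2 (103 and 244). For 2210010C04Rik these were vehicle mouse 2 and testosterone mice 2 and 3 after withdrawal. The filter thus helped to set this upward result. Without testosterone mice 1 and 2 the list was not called and its median was 0.89 in place of 1.84. None of 19 endocrine pancreas genes and 0 of 13 acinar and pancreatic transcription factors lay above the same limit in either mouse, a comparison of signals with no test.

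**Figure D3:**
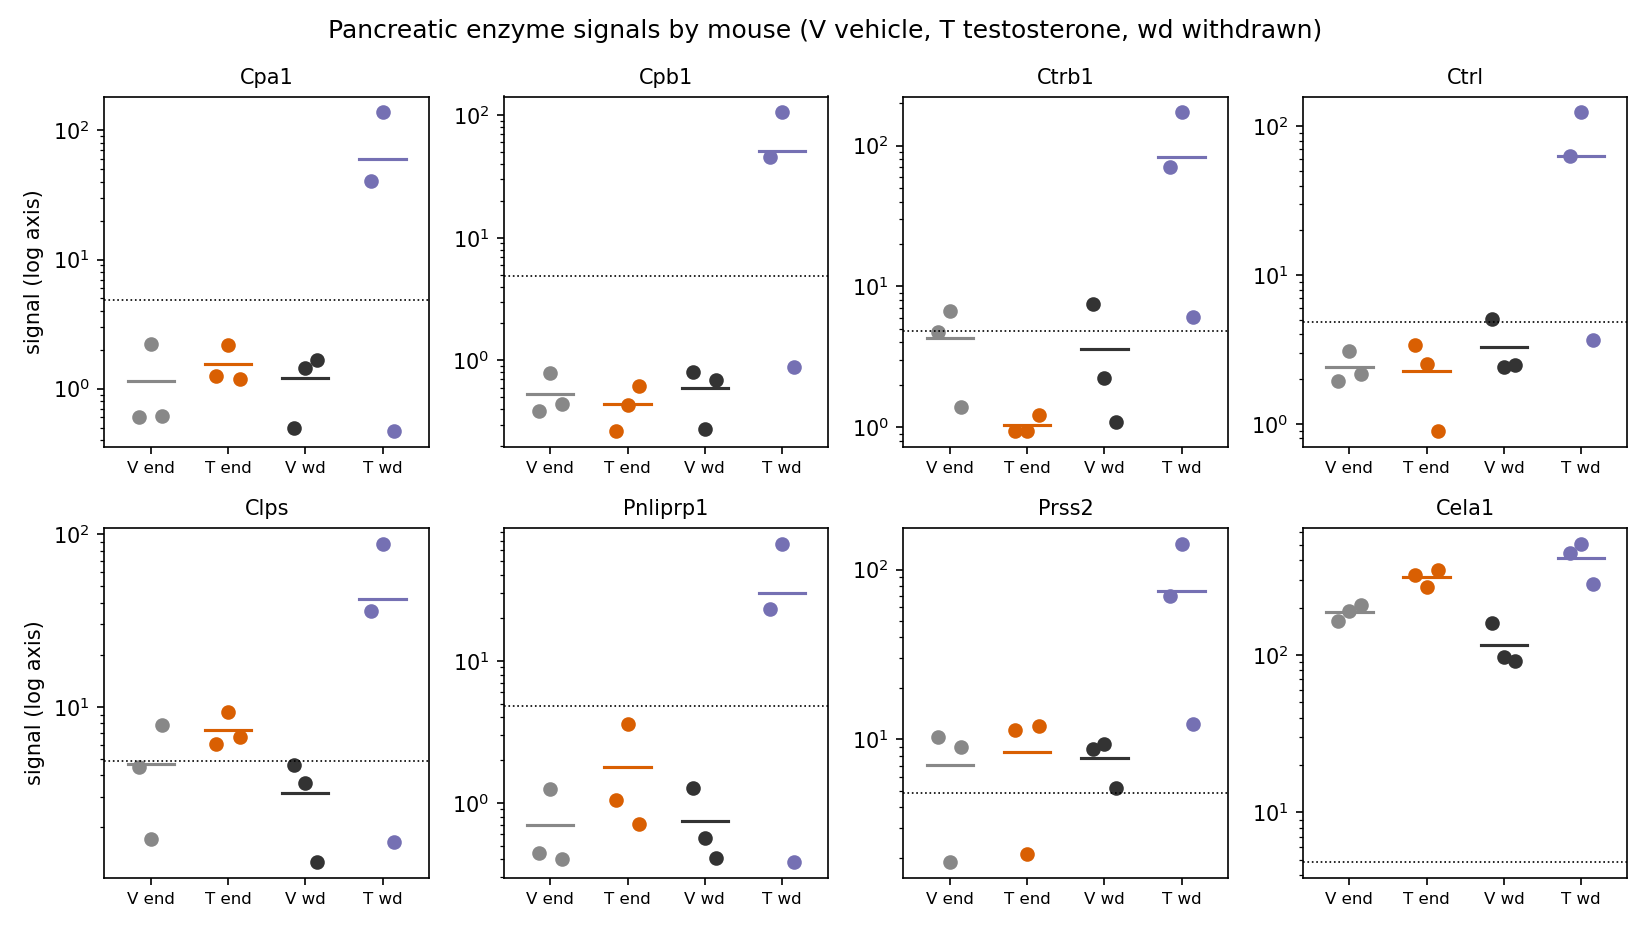
Signals of 8 pancreatic enzymes on a logarithmic axis, with 1 point per mouse, a line at the mean of each group of 3 and a dotted line at the floor of 4.84. Cpa1 reads 40.3 and 138 in testosterone mice 1 and 2 after withdrawal and at most 2.22 in the other mice, whereas Cela1 was measured in all mice, at 188 ± 22.6 and 311 ± 37.8 at the end of treatment and 116 ± 38.1 and 413 ± 117 after withdrawal.

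Sult2a2, Cyp2b13, Sult3a1, Cyp4a12a, Hsd3b5, Slc22a27, Slc22a26, Cyp2b9, Cyp2d9 and Mt2 had the largest changes among genes called in the same direction at both times. There were 220 such genes, 105 higher and 115 lower, against 18.66 and 18.82 that independent lists of these sizes would share; Fisher's exact test over genes, which are not independent, gave p = 5.52e-57 and p = 8.79e-66. The count was 53 with the actin ratio in the fit and 122 without testosterone mice 1 and 2 (62 higher, 60 lower). The balance was 125 higher and 90 lower with median centring, 72 and 72 with no filter, and 78 and 77 without vehicle mouse 2 of the withdrawal time. Of 21 male-biased genes 17 were called in the same direction at both times, and of 37 female-biased genes 27. The log2 changes of the 2 times correlated across genes at Pearson r = 0.574 and Spearman rho = 0.227. Another 9 genes were called in opposite directions. Of these, Phlda1, Cish and Foxa2, higher at the end and lower after withdrawal, were named after their values were seen and held both calls without any single array, whereas the other 6 lost a call at 1 time or the other when an array was left out.

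The effect of testosterone itself differed between the times for a smaller set of genes, tested as the effect after withdrawal minus the effect at the end of treatment. Clock genes also differed between the times in both treatments, and the hour of collection is not given. An effect that depends on the conditions of collection therefore cannot be told apart from one that changed with withdrawal. Igfbp1 had the largest positive difference (4.80 ± 0.84, adjusted p = 0.0116; 5.61 without testosterone mouse 2 and 3.93 without testosterone mouse 3 of the withdrawal time), followed by Bcl6 (3.02 ± 0.35, adjusted p = 0.000477), which read 56.9 ± 7.03 and 58.7 ± 20.5 at the end but 22.3 ± 5.03 and 179 ± 43.0 after withdrawal in vehicle and testosterone mice. Elovl3 (2.30), the ephrin Efna1 (1.89), Herpud1 (1.79) and the glycosyltransferase C1galt1 (1.68) also had positive differences. The negative differences were led by Phlda1 (-3.36 ± 0.23, adjusted p = 2.16e-06), which rose 4.09-fold at the end and fell 2.50-fold after withdrawal, and Cish (-3.32 ± 0.30, adjusted p = 4.81e-05), followed by Myc (-2.70), the transcription factor Foxq1 (-2.24), Wsb1 (-2.05) and Ccdc25 (-1.97).

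In total 158 genes differed by limma, 57 upward and 101 downward, and 1580 had an unadjusted p under 0.05. Of the genes higher at the end, 77 had a called difference opposite in sign to their change at the end, and of those lower at the end 46. These include genes that passed zero and reversed, such as Phlda1 and Cish. Without vehicle mice 1, 2 and 3 of the end of treatment in turn the count was 67, 83 and 265, and without the testosterone mice 1, 2 and 3 of that time 72, 56 and 83. Without vehicle mice 1, 2 and 3 of the withdrawal time it was 300, 46 and 26, and without the testosterone mice 1, 2 and 3 of that time 542, 38 and 51. With the actin ratio in the fit 1 gene was called. Upward differences outnumbered downward ones with the mean of probe sets (63, 58) and with every probe set tested (321, 257).

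**Figure D4:**
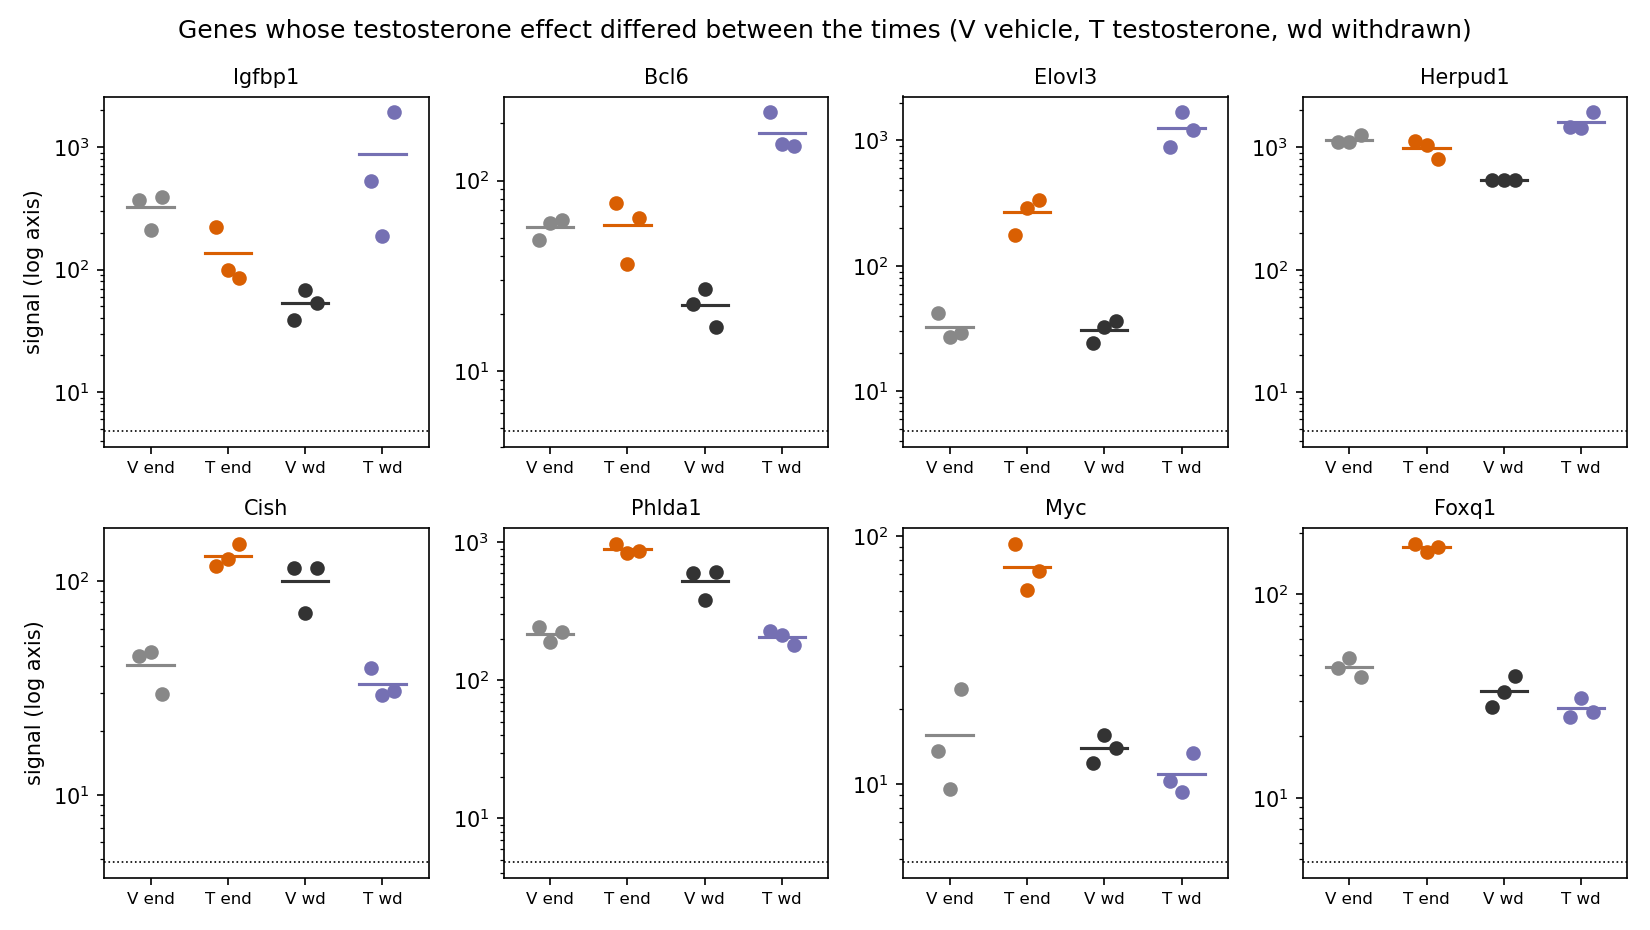
Signals of 8 genes whose testosterone effect differed between the times, on a logarithmic axis, with 1 point per mouse, a line at the mean of each group of 3 and a dotted line at the floor of 4.84. Bcl6 means were 56.9 and 58.7 at the end of treatment and 22.3 and 179 after withdrawal, and Phlda1 means were 218 and 892 and then 528 and 208, in vehicle and testosterone mice.

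By list, the difference between the times was upward for cholesterol synthesis, macrophage markers and acute phase genes, at camera adjusted p = 6.17e-06 each and, with an estimated correlation, adjusted p = 0.477 each. By limma 2 of 19 cholesterol synthesis genes, 1 of 29 acute phase genes and 0 of 22 macrophage markers were called (5, 8 and 0 upward adjusted over the list alone). The actin ratio in testosterone and vehicle mice was 2.11 and 1.52 at the end, and 1.62 and 1.77 after withdrawal. For acute phase genes vehicle mouse 2 of the end also stood apart, with 5040 for Saa1 against 379 and 247. The difference was also upward for hepatocyte core genes (adjusted p = 5.37e-05), male-biased genes (0.000148), bile acid genes (0.00156), phase II conjugation (0.00873), exocrine enzymes (0.0175), steroid metabolism (0.0191), cell division (0.0341), female-biased genes (0.0462), the unfolded protein response (0.0479) and xenobiotic P450s (0.0497). All of these were lost with an estimated correlation, at adjusted p = 0.206 to 0.601. Of male-biased genes 3 had a called difference upward, Bcl6 and Elovl3 among them, and 1 downward; of female-biased genes 2 had one upward, such as Cyp17a1 (1.29), and 1 downward. Median, mean and test of the difference differed in sign for interferon (0.03, -0.05, upward), clock (-0.10, -0.02, upward), fat cell (-0.03, 0.07, upward) and erythroid genes (-0.05, 0.02, upward).

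Between the times within a treatment, genes of the circadian clock were among those with large changes in vehicle mice and in testosterone mice. Dbp, a clock output factor, fell 55.4-fold in vehicle mice (658 ± 140 to 12.3 ± 4.26) and 41.7-fold in testosterone mice (797 ± 69.0 to 23.8 ± 20.1) from the end of treatment to the withdrawal time. Arntl, the clock activator Bmal1, rose 7.11-fold and 6.05-fold, and the deubiquitinase Usp2 fell 7.82-fold and 9.95-fold. In vehicle mice Tubb2a (7.55-fold), Hao2 (8.51-fold), Serpinb1a (6.19-fold) and the glycogen regulator Ppp1r3c (6.18-fold) also rose, and Slco1a1 (261 ± 62.7 to 41.8 ± 56.2) and the macrophage receptor Marco (6.94-fold) fell. In testosterone mice Chka (6.00-fold), Nfil3 (5.50-fold) and G0s2 (4.86-fold) rose, and Per3 (at least 9.75-fold), Lpin1 (9.71-fold) and Myc (6.82-fold) fell. The log2 change of Slco1a1 was -3.62 with all mice, -4.80 without vehicle mouse 1 and -2.57 without vehicle mouse 2 of the withdrawal time, and that of Dbp in testosterone mice -5.38, and -6.03 without mouse 3 of that time.

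In vehicle mice 1288 genes differed between the times by limma, 795 higher and 493 lower after withdrawal, and in testosterone mice 785, with 402 higher and 383 lower. Median centring turned both balances, to 473 higher and 708 lower in vehicle mice and 292 higher and 453 lower in testosterone mice. The latter was also turned by a floor at the 50th percentile (366, 367) and without testosterone mouse 1 of the withdrawal time (405, 435). Of these genes 167 were higher and 130 lower in both, against 44.28 and 26.16 for independent lists. The vehicle count was 624 without vehicle mouse 2 and 584 without vehicle mouse 3 of the withdrawal time. The testosterone count was 454, 520 and 498 without testosterone mice 1, 2 and 3 of the end of treatment, and 483 and 482 without mice 2 and 3 of the withdrawal time. With the actin ratio, which was 1.52, 1.77, 2.11 and 1.62 in vehicle mice at the end and after withdrawal and testosterone mice at the end and after withdrawal, in the fit, the counts were 232 and 110 (in testosterone mice 51 higher, 59 lower). Without testosterone mice 1 and 2 of the withdrawal time, the testosterone count was 313.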

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

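Of the tests in this part, those on splits with the shared effect removed, on probe sets of the same gene, on pancreas tissue and Cela1, and on the acute phase genes without vehicle mouse 2 were chosen only after the result was seen. The effect of testosterone differed between the times in 158 genes by the test of the difference itself. The largest differences, after withdrawal minus end of treatment, were those of Phlda1 (-3.36), Cish (-3.32), Myc (-2.70), Hao2 (-2.31), Foxq1 (-2.24), Ampd2 (-2.09), Gadd45g (-2.07), Wsb1 (-2.05), Ccdc25 (-1.97) and Lpin1 (-1.93), and on the other side Igfbp1 (4.80), Bcl6 (3.02), Elovl3 (2.30), Efna1 (1.89), Il1b (1.83), Herpud1 (1.79), C1galt1 (1.68), Ctse (1.56), Met (1.54) and Slc22a7 (1.43). In testosterone mice Hao2 read 2.38, 3.91 and 5.07 at the end and 7.43, 2.90 and 16.7 after withdrawal. Some of these signals lay under the floor at each time. In vehicle mice it read 29.0, 48.3 and 59.9 and then 340, 431 and 354. Its difference therefore cannot be told apart from a rise in vehicle mice over testosterone signals held by the floor. Cish is induced by STAT5 and Bcl6 represses STAT5 targets, and both act downstream of growth hormone.

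Some of these calls were lost when any of several single arrays was left out, while the differences kept their sign. Hao2 was not called (-2.38 to -1.91) without vehicle mouse 1 or 2 or testosterone mouse 1, 2 or 3 of the end of treatment, or vehicle mouse 2 or 3 or testosterone mouse 2 of the withdrawal time. Ampd2 was not called (-2.27 to -1.76) without these or testosterone mouse 3 of the withdrawal time, and its sign turned (0.10, not called) when probe sets with shared-probe suffixes were left out. Gadd45g was not called (-2.29 to -1.69) without any single mouse of the end of treatment, or vehicle mouse 1 or 3 or testosterone mouse 2 of the withdrawal time. Slc22a7 was not called (1.21 to 1.497) without vehicle mouse 1 or 2 or any single testosterone mouse of the end, or vehicle mouse 2 or testosterone mouse 2 or 3 of the withdrawal time. Met was not called (1.32 to 1.53) without vehicle mouse 1 or 2 or testosterone mouse 2 or 3 of the end, or mouse 2 or 3 of either treatment at the withdrawal time. Ctse was not called (1.39 to 1.55) without testosterone mouse 1 or 2 of the end, or vehicle mouse 2 or 3 or testosterone mouse 3 of the withdrawal time. Without vehicle mouse 2 or 3 or testosterone mouse 2 of the withdrawal time, Il1b (1.61 to 1.87) and Lpin1 (-2.01 to -1.81) were not called, nor was Il1b without vehicle mouse 1 of the end (1.77).

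For the comparisons of 3 mice with 3, the 10 possible splits are too few for a share under 0.05. The real split called 1258 genes at the end of treatment and the highest other split 1, and after withdrawal the counts were 433 and 0. Between the times they were 1288 and 1 in vehicle mice and 785 and 0 in testosterone mice, with 1 split of 10, the real one, as high in each case. For the difference between the times, 3 of 100 splits within the times called as many as the real 158 genes, the highest 1164 with the labels of the withdrawn mice exchanged, which points to a structure of the samples: splits that mix treatments carry the effect shared by both times into the spread or the difference, so this count decides nothing. After removal of the effect shared by both times, 1 of 100 splits, the real one, called 165 genes, and the highest other called 2. This share is under 0.05, but the shared effect was estimated with the real labels. The real split and the others are therefore not fully alike, and chance is not excluded. For genes changed in the same direction at both times, 1 of 100 splits, the real one, gave 220. The highest other, that with the labels of the withdrawn mice exchanged, gave 9. The remaining splits mix treatments, which removes the calls of each time. The share therefore speaks against the absence of any treatment effect, and does not test whether the times agree beyond chance.

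Digestive enzymes of the pancreas stood out in testosterone mice 1 and 2 after withdrawal, where 7 and 12 of 25 enzymes lay above 5 times the highest vehicle signal or 5 times the floor of 4.84, whichever was higher. Pancreas tissue carried along with the liver does not account for Cela1 in testosterone mice without the other enzymes, where it lay above every vehicle mouse of its time in 4 of 4. After withdrawal this covers mouse 3 alone, at 282 against at most 160 in vehicle mice. In mice 1 and 2, which read 446 and 509, a part of the Cela1 signal from such tissue is not excluded. For the other enzymes such tissue and enzyme expression in liver cells cannot be told apart: the ratio of mouse 2 to mouse 1 had a median of 2.30 over 7 enzymes with an SD of 0.333 in log2, as a single source in differing amounts would give, but a shared program of expression might give the same. Endocrine genes such as Ins2 (1.76 and 2.63) and 13 acinar and pancreatic transcription factors stayed under the limit, but the expected signal of scarce cell types in a small piece of tissue is unknown. An effect of testosterone on these enzymes, which the design names, also stays open, with 1 of 3 mice showing none of them but Cela1.

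More genes changed at the end of treatment than after withdrawal, and the ratio of 3' to 5' actin signal was 2.11 in testosterone mice at the end against 1.52 in vehicle mice. With this ratio in the fit the order turned, to 78 and 263 genes in place of 1258 and 433. The ratio separated the groups at the end but not after withdrawal, which widens the error mainly at the end. The turned order therefore decides nothing, and RNA integrity stays open as a cause of the higher count at the end. Among called genes with another called probe set, this was called in the opposite direction in 24 of 214 (11.2%) at the end and 0 of 57 after withdrawal (two-sided Fisher's exact p = 0.00348), as RNA integrity or its copying would give for a part of the changes, though transcripts of a gene that change differently might give the same. A slope on the actin ratio within groups correlated with the changes at r = 0.026 over genes, and 16 of 36 arrangements of the arrays gave as much (one-sided exact p = 0.444), which decides nothing. With the ratio in the fit, which largely overlaps with treatment at the end, the cholesterol synthesis list was no longer called (median -0.05 in place of -0.56), so for it both stay open, as they do for macrophage markers (-0.32 in place of -0.68) and interferon genes (-0.39 in place of -0.49), whose lists had adjusted p = 0.34 each with an estimated correlation. The 2 lists parted after withdrawal, when the actin ratio was 1.62 in testosterone and 1.77 in vehicle mice. Interferon genes were lower then too (8 of 27, 0 higher, median -0.60), whereas macrophage markers had 0 calls. The Gapdh ratio went the other way (0.844 against 0.797), so this does not settle the end of treatment. With the actin ratio in the fit at the end, 11 male-biased genes were still called higher and 15 female-biased genes lower, gene by gene. This counts against RNA integrity as the whole cause for these genes, while the lists themselves had adjusted p = 0.139 and 0.0227 with an estimated correlation.

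Acute phase genes were lower in testosterone mice at the end of treatment, when vehicle mouse 2 read 5040 for Saa1 against 379 and 247 in the other vehicle mice. This mouse alone does not explain the pattern, since 11 of the 12 genes were called lower without it, Orm1 being the exception (-0.35 with it and -0.21 without it). It did set the size of some changes, such as that of Lcn2 (-3.81 with it and -2.23 without it). Adding the actin ratio to the fit left 4 genes called lower, which counts against RNA integrity as the whole cause for these 4, but for the list (median -0.26 in place of -0.35, adjusted p = 0.34 with an estimated correlation) it stays open. An effect of testosterone stays open as untested.

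Outside the genes tested, probe sets without a single gene symbol that passed the signal filter numbered 972, of which 182 were called at the end of treatment and 50 after withdrawal. They were set aside because their signal cannot be assigned to 1 gene, and no explanation was tested for them.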

How the results depend on the processing

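The alternatives chosen after seeing the data were the actin 3' to 5' ratio as a covariate, leaving out testosterone mice 1 and 2 of the withdrawal time, running lists on the contrasts between times, and running the alternatives on lists other than the exocrine, male-biased and female-biased ones. Over all settings but every probe set tested and the 2-fold threshold, 5101 values of named genes were compared with those reported. Of these 4355 had the same direction and side of the threshold, 700 were no longer called, 8 became called and 38 changed sign. Of 243 gene values 229 were called, 89 of them under every setting in which they were compared, and 18 reversed under at least 1. Some settings gave no value for a part of them: 186 were compared with shared-probe suffixes left out and 191 with the filter at the 75th percentile. Where no reason is given, the cause was not tested. Signals near the floor limit folds to lower bounds. The signal filter, which asks for a signal above the array's median on at least 3 arrays, left 22 of 25 pancreatic enzymes untested in the main fit.

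With each array left out in turn, which leaves 2 mice in a group assumed to vary like the others, counts ranged from 789 to 1137 at the end of treatment, 236 to 634 after withdrawal, 26 to 542 for the difference between the times, 584 to 1311 and 454 to 840 between times in vehicle and testosterone mice, and 155 to 231 for both times. List medians ranged from -0.50 to 0.19 (exocrine enzymes, end), 1.66 to 2.09 (exocrine, withdrawn), 1.44 to 1.78 and 2.38 to 2.96 (male-biased), and -1.92 to -1.63 and -2.004 to -1.414 (female-biased). Genes whose sign turned were Bcl6 at the end (-0.24 to 0.30), Stat5b at the end (-0.31 to 0.055), Igf1 (-0.013 to 0.126) and Xist (-0.16 to 0.037) after withdrawal, and the differences of Cux2 (-0.15 to 0.37), Ghr (-0.139 to 0.023) and Stat5b (-0.317 to 0.048), none of them called.

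No filter, which adds genes near background, gave 286 after withdrawal, 37 for the difference, 792 and 490 between times, 144 for both times and 0.00 for the exocrine enzymes at the end. Testing every probe set, which adds features, gave 2344 at the end, 578 for the difference (55.5% upward against 36.1%), 1991 and 1230 between times. The difference gave 72 with no variance trend, 693 with array weights and 55 with the replicate block, and array weights gave 866 after withdrawal and 0.067 for Bcl6 at the end. A 2-fold threshold, stricter by construction, gave 185, 124, 70, 205 and 159 in the order of the contrasts and 65 for both times. The replicate numbers did not pair the mice: 0 of 12 same-numbered pairs correlated above 0.1 (-0.194 to 0.006, others -0.153 to 0.183).

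Median centring moved the balance of directions: 264 higher and 167 lower after withdrawal (61.3% higher against 45.7%), 473 and 708 between times in vehicle mice (40.1% against 61.7%), 292 and 453 in testosterone mice (39.2% against 51.2%), and 125 and 90 at both times (58.1% against 47.7%). It also reversed uncalled values of Bcl6 at the end (0.015), Xist after withdrawal (0.011) and the difference of Ghr (0.003). A floor at the 50th percentile reversed the difference of Cux2 (-0.14). The mean of probe sets gave -0.25 for Hnf4a and -0.29 for Ghr at the end, -0.093 for Igf1 after withdrawal, and differences of 0.51 for Stat5b, 0.30 for Hnf4a and 0.49 for Ghr. Leaving out shared-probe suffixes gave -0.016 for Hsp90aa1 at the end, -0.31 for Hnf4a, 0.005 for Xist and -0.25 for Igf1 after withdrawal, and differences of -0.13 for Igf1 and 0.10 for Ampd2.

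With the actin ratio as a covariate the counts were 78, 263, 1, 232 and 110 in the order of the contrasts and 53 at both times; at the end of treatment the ratio overlaps with treatment, which widens the error. Values at the end became 0.12 for Stat5b, 0.015 for Mvk, 0.022 for Sqle, 0.003 for Stab2 and 0.004 for Bgn, and Xist after withdrawal became 0.00. Without testosterone mice 1 and 2 of the withdrawal time, which leaves 1 mouse assumed to vary like the other groups, the counts were 250 after withdrawal, 313 between times in testosterone mice and 122 at both times. The exocrine enzyme median was 0.89 and no longer called, and the differences were -0.15 for Cux2 and 0.12 for Ghr.

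Gene list calls also moved with the setting, given here as medians. After withdrawal steroid metabolism was not called with a filter at the 75th percentile (0.07), the mean of probe sets (0.06) or shared-probe suffixes left out (0.06), bile acid genes with the 75th percentile filter (0.07), B cells with a floor at the 50th percentile (-0.45) or the mean of probe sets (-0.76), and stellate (-0.23) and fetal liver genes (-0.76) with shared-probe suffixes left out. At the end phase II conjugation was not called with the 75th percentile filter (-0.01), the mean of probe sets (-0.12) or the actin ratio (0.05). Lists that became called at the end were sex chromosome genes with quantile normalization (0.32), xenobiotic P450s with median centring (-0.10) or only the compared groups (-0.13), fetal liver genes with median centring (-0.40) or the mean of probe sets (-1.29), stellate genes with no filter (-0.17), shared-probe suffixes left out (-0.16) or array weights (-0.18), and erythroid (1.34) and hepatocyte core genes (0.19) with the actin ratio. After withdrawal immediate early genes became called with a floor at the 50th percentile (0.19), the mean of probe sets (0.23) or without testosterone mice 1 and 2 (0.69), cholesterol synthesis with the actin ratio (-0.21, downward) or without those mice (0.08, upward), and clock genes without those mice (0.11).

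Without single mice of the end, lists became called as follows: xenobiotic P450s without vehicle mouse 1 (-0.10) or testosterone mouse 1 (-0.19) or 3 (-0.10), sex chromosome genes without vehicle mouse 1 (0.37) or 3 (0.36) or testosterone mouse 2 (0.32), stellate genes without vehicle mouse 2 (-0.20) or 3 (-0.17), fetal liver genes without vehicle mouse 2 (-0.51) or 3 (-0.57), erythroid genes without vehicle mouse 3 (0.92) or testosterone mouse 2 (0.84), fatty acid oxidation (0.19) and neutrophils (-1.04) without vehicle mouse 3, and gluconeogenesis without testosterone mouse 1 (-0.17). After withdrawal they were immediate early genes without vehicle mouse 2 (0.16) or 3 (0.26) or testosterone mouse 2 (0.45), and cholesterol synthesis without testosterone mouse 3 (-0.14).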

Other observations

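The lists on the contrasts between times were run only after the data were seen. In vehicle mice, 11 of 21 male-biased genes, 16 of 22 macrophage markers and 11 of 19 cholesterol synthesis genes were lower at the withdrawal time than at the end of treatment, with 0 higher in each. Camera gave adjusted p = 2.12e-06, 1.13e-12 and 4.18e-11, and adjusted p = 0.484 for each with an estimated correlation. Between the same groups the pyruvate carboxylase 3' to 5' ratio went from 6.06 ± 1.35 to 14.1 ± 4.41 (exact permutation p = 0.1) and the actin ratio from 1.52 ± 0.108 to 1.77 ± 0.155 (exact permutation p = 0.2). In testosterone mice 12 of 37 female-biased genes were higher and 1 was lower (adjusted p = 0.00061, and adjusted p = 0.58 with an estimated correlation), while the pyruvate carboxylase ratio went from 18.8 ± 2.64 to 11.5 ± 3.32 and the actin ratio from 2.11 ± 0.077 to 1.62 ± 0.179 (exact permutation p = 0.1 each).

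Of 17 circadian clock genes, 4 were higher and 10 lower at the withdrawal time in vehicle mice and likewise in testosterone mice. Camera gave adjusted p = 0.000182 and 0.000202, and adjusted p = 0.484 and 0.438 with an estimated correlation, and 13 genes, 4 higher and 9 lower, were called in the same direction in both treatments. The hour at which livers were taken is not given in the sample labels.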
